A study of Mus musculus with 8 samples.

How the data were processed

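RNA was measured in 8 libraries, each from the pharyngeal (branchial) arches and looping heart of an individual mouse embryo at 10.5 days post coitum, 4 from Pygo2 mutants and 4 from wild-type littermates. Per the labels' protocols, the tissue was dissected by hand, frozen in liquid nitrogen and extracted with TRIzol, and 300 ng of total RNA per sample went into a stranded total RNA library kit (Illumina TruSeq) with ribosomal RNA depletion by RiboZero. Such a library also holds RNA without a poly(A) tail, such as replication-dependent histone mRNA and small nucleolar RNA, so the recovery of these RNAs can move their measured levels. Each embryo is a separate biological sample, and the labels do not say which part of Pygo2 was altered.

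Per the submitters' processing notes, TopHat2 2.0.11, HTSeq 0.6.1 and edgeR 3.14 were used with the mm10 build of the mouse genome. The gene annotation, the strand setting of the counting and the read filters are not given in the sources used here, so counts of overlapping or near-identical genes, including the histone and ribosomal protein families, are uncertain. The authors deposited a table of raw counts per gene symbol for 23420 genes, with whole numbers and a different total in each library. A second deposited table holds a scaled signal, in which the authors divided each raw count by 1 constant per library. It keeps 13631 genes, the same 13631 as a limit of more than 1 CPM in at least 4 libraries, and its scaling equals TMM factors computed on those genes. The third deposited table is the authors' own comparison of mutant with wild-type, with a log2 fold change, the mean log2 CPM, a linear fold, a p-value and a false discovery rate per gene. Beside it stands a list of 165 gene ontology terms, with how many of the first 500 genes carry each term, the number expected and a p-value; the tool behind it is not given in the sources used here. The classic exact test of edgeR on the 13631 genes gave the p-values of the authors' deposited table to within a relative difference of 0.0562. The deposited fold changes and p-values are quoted only as the authors' values, and all other values below were computed from the raw counts.

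Library totals ran from 2.08e+07 to 2.82e+07 counts. The common biological coefficient of variation between embryos was 26.3%. Gene symbols were matched to the GENCODE M21 annotation of the same build (GRCm38, mm10) for positions and lengths: 21777 symbols matched directly, 1277 through an older symbol and 366 did not match.

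Genes were kept by the filterByExpr function of edgeR (4.0.16, in R 4.3.3), which left 14861 genes. Libraries were scaled with TMM, and mutants were compared with wild-type embryos by the quasi-likelihood test of edgeR (glmQLFit and glmQLFTest, two-sided) with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counts as a call. CPM values use the TMM-scaled library sizes and log2 CPM a prior count of 2. The difference in Pygo2 CPM was also tested by an exact permutation test over the 70 ways of assigning 4 of the 8 libraries to a group. Intervals of log2 fold changes are 95% intervals from the standard error and a t distribution with 6 degrees of freedom.

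A set of 31 gene lists was fixed before the data were examined, along with the design, the rule for naming genes and most of the other settings tried. The lists cover Wnt signalling, heart and arch development, other signalling pathways, markers of other cell types in the dissection, cell cycle and stress genes, and RNA classes that report on handling. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and p-values were adjusted over the 29 lists tested. The liver list had 4 tested members and the mitochondrial genome list 0, so neither was tested. Because genes of a list can vary together between embryos, camera with a correlation estimated per list and fry were run beside it. A call by fry would mean that the genes of a list moved 1 way on balance, with no comparison to other genes. A list score is the mean log2 CPM of the tested members in a library.

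Genes are named in the text by a rule with 4 parts. It takes 12 genes of Wnt signalling and heart development in every case (Pygo2, Pygo1, Bcl9, Bcl9l, Ctnnb1, Axin2, Lef1, Tcf7, Nkx2-5, Isl1, Tbx1 and Hand2), up to 10 genes per direction that passed the threshold with at least 1 CPM and no overlap between groups, and up to 4 passing members per list or otherwise the 2 with the smallest p. Because fewer than 10 genes passed, the 10 with the smallest p in each direction and a mean of at least 1 CPM are named too, as values that did not pass. Of the genes this rule takes, 5 are not reported here and were not replaced by others. Xist and Y-linked genes were used only to look at embryo sex.

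The labels give both groups the numbers 1 to 4. The deviations of same-numbered libraries from their group means had correlations across genes of 0.556, 0.185, 0.676 and 0.186, all above 0.1, the limit set for treating the numbers as pairs, and 4 of the 8 libraries correlated best with the library of their own number. The pairing is thus inferred from the data; the labels do not say what the numbers stand for. The fit without the number had been set beforehand as the main one and was kept. Variation shared by number stays in its error and can make its p-values too large. A fit with the number as a block was made beside it, and its value is given where it changes a call. A chi-square test of the counts of genes with a total of at least 100 gave 21.9 to 154 per degree of freedom over the 28 pairs of libraries, so no library repeats another.

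The test code was run on simulated counts with the means and library sizes of this comparison, with 200 of 14735 genes changed. It recovered 12% of the genes changed 1.5-fold, 54% of those changed 2-fold, and 84% of those changed 3-fold and of those changed 4-fold, with 4 false calls among 121. A simulated list of 25 genes lowered by 0.4 on the log2 scale had a camera p of 2.2e-08 and a list of 25 unchanged genes 0.405. Genes were simulated independently of each other, so this does not show how camera behaves for lists whose genes vary together. The estimated correlation was 0.475 in the histone list and 0.936 in the contractile list. With 200 genes changed, the adjusted threshold is also easier to reach than with fewer, so recovery can be lower in the data. Alternatives were RLE size factors, DESeq2 (1.42.0), the likelihood ratio test of edgeR, limma-voom, other low-count filters, the block, covariates for embryo sex and heart tissue, removal of erythroid genes, a threshold of 0.1, and each library left out in turn. Alternatives added after the data were seen removed structural RNAs, took the neural list as a covariate, used the exact test of edgeR, or left out the pair numbered 4.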

Results

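Gene expression was compared between Pygo2 mutant and wild-type mouse embryos at 10.5 days post coitum, a stage at which the pharyngeal arches are being patterned and the heart tube has looped. Pygo2 encodes a PHD-finger protein that binds Bcl9 and Bcl9l and through them takes part in transcription by β-catenin. The arches were dissected together with the heart from 4 wild-type and 4 mutant littermates, and total RNA depleted of ribosomal RNA was sequenced from each embryo. The wild-type libraries held 2.23e+07, 2.35e+07, 2.08e+07 and 2.82e+07 counts and the mutant libraries 2.33e+07, 2.78e+07, 2.69e+07 and 2.73e+07 counts. The comparison asks which genes differ in arch and heart tissue when Pygo2 is mutated, in a series whose title concerns heart defects and tissue-specific Wnt signalling.

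Pygo2 itself was the gene that fell. Its level was 51.0 ± 5.2 CPM (SD, n = 4) in wild-type embryos and 19.3 ± 1.99 CPM (SD, n = 4) in mutants, so 37.9% of the wild-type level remained, a 2.64-fold reduction. The 4 wild-type libraries held 1275, 1279, 1004 and 1189 Pygo2 counts and the 4 mutant libraries 526, 556, 492 and 478, without overlap and with the mutant below its same-numbered wild-type in 4 of 4 pairs. The log2 fold change was -1.40 (SE 0.12, edgeR quasi-likelihood adjusted p = 0.00805). The exact permutation test of the CPM values gave p = 0.0286 (two-sided), the smallest that 70 assignments allow. It treats the libraries as exchangeable and leaves out the inferred pairs. Every gene without overlap between groups reaches this value, and 155 genes had no overlap. Pygo2 (ENSMUSG00000047824.13) is a protein-coding gene on the plus strand of chromosome 3, from 89430214 to 89435128 in mm10. Counts were summed over the whole gene, so they do not show whether the remaining RNA carries the altered part. With fewer libraries the adjusted p passed 0.05: it was 0.0549 without wild-type 1, 0.0739 without wild-type 2, 0.0973 without mutant 2, 0.0694 without mutant 3, 0.0636 without mutant 4 and 0.140 without both libraries numbered 4. The log2 fold change stayed between -1.46 and -1.35 over the 8 fits that left out 1 library.

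**Figure D1:**
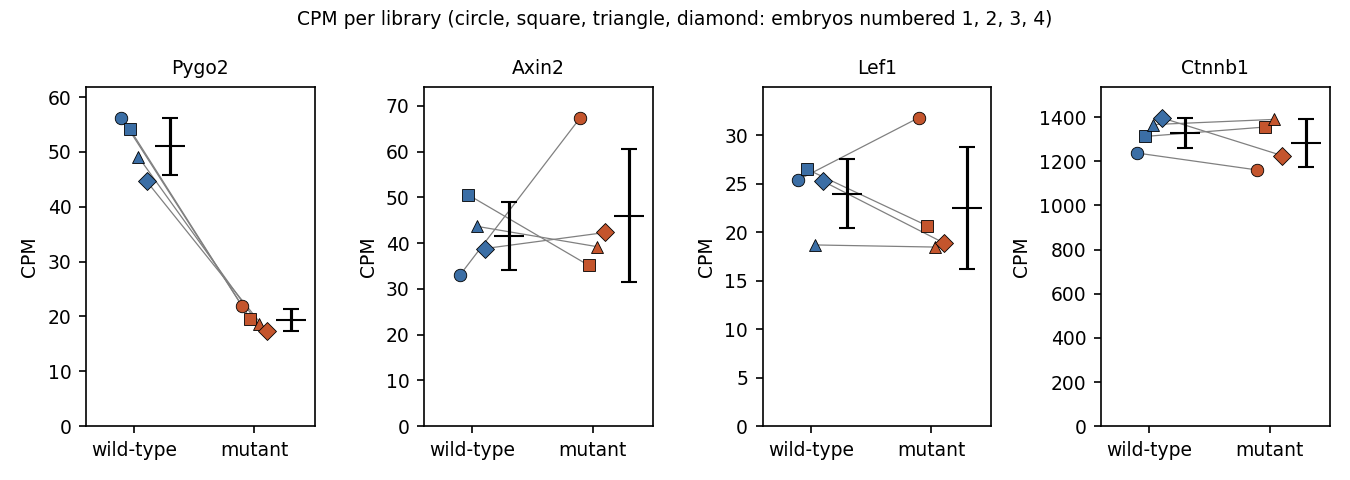
CPM of Pygo2, Axin2, Lef1 and Ctnnb1 in each library, with lines joining libraries of the same number and bars showing the mean ± SD of 4 libraries per group. Pygo2 was 51.0 CPM on average in wild-type and 19.3 CPM in mutant embryos without overlap, and the 3 Wnt pathway genes overlapped between groups.

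No other gene passed the threshold among the 14861 tested. With the quasi-likelihood test of edgeR 0 genes rose and 1 fell, and the second smallest adjusted p was 0.99998. At an unadjusted p under 0.05 there were 193 genes (1.30% of those tested), 72 higher and 121 lower in mutants. That is a smaller share than the 0.05 expected by chance alone from independent libraries. DESeq2, the likelihood ratio test of edgeR and limma-voom also called 0 higher genes and 1 lower gene, Pygo2; they had 252, 167 and 210 genes at an unadjusted p under 0.05. With the replicate number as a block the call was again Pygo2 alone (adjusted p = 0.00241), and 745 genes (5.01%) had an unadjusted p under 0.05. Every mutant library lay above every wild-type library for 72 genes (0.484%) and below for 83 genes (0.559%), against 2.86% of genes in both directions together by chance if libraries were exchangeable. Libraries of the same number vary together, which makes such a separation rarer: in the 7 other splits that part all pairs, 0.518% to 2.10% of genes were separated, and 1.04% in the real split.

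The authors' deposited table of the same comparison covers 13631 genes and gives Pygo2 a log2 fold change of -1.40 and a false discovery rate of 5.88e-16. Pygo2 is also its only gene under 0.05, so the 1 called gene is shared with the fit above. The next smallest value in the authors' deposited table is 0.498, for Tmod4, which is named here because of its place in that table. Across the 13631 genes in both, the log2 fold changes of the deposited table and of the fit had a Pearson correlation of 0.99995 across genes, which are not independent replicates.

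Wnt target genes did not differ as a list, and 0 genes of the pathway other than Pygo2 passed the threshold. Among 19 measured Wnt target genes, 10 were higher and 9 lower in mutants, with a median log2 fold change of 0.01 and a mean of -0.07 (camera direction lower, adjusted p = 0.612). Axin2, a feedback inhibitor and common Wnt readout, was at 41.5 ± 7.45 CPM in wild-type and 46.0 ± 14.5 CPM in mutants (SD, n = 4 each), a log2 fold change of 0.15 with a 95% interval from -0.38 to 0.68. Lef1, a transcription factor that binds β-catenin, was at 0.94 of its wild-type level (log2 -0.09, interval -0.58 to 0.39), and Tcf7, of the same family, was at 0.22 on the log2 scale (-0.17 to 0.62). The members with the smallest p were Dkk1, a secreted Wnt inhibitor, and Sp5, a transcription factor (log2 -0.96, SE 0.46). Dkk1 was at 15.6 ± 3.83 CPM in wild-type and 8.07 ± 3.12 CPM in mutants (SD, n = 4 each) without overlap, a log2 fold change of -0.95 with an interval from -1.70 to -0.21. Adjusted over the list alone 0 Wnt target genes passed, and with the block 1 did, Dkk1, which was lower in 4 of 4 pairs.

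Genes whose products act with Pygo2, and its paralog, did not pass the threshold. Ctnnb1, which encodes β-catenin, was at 1328 ± 69.7 CPM in wild-type and 1282 ± 108 CPM in mutants (SD, n = 4 each; log2 -0.05, interval -0.30 to 0.20). Bcl9 (log2 0.15, interval -0.31 to 0.61) and Bcl9l (log2 0.45, interval -0.24 to 1.14) overlapped between groups. Pygo1, the paralog of Pygo2, was at 4.66 ± 3.30 CPM in wild-type and 2.24 ± 0.391 CPM in mutants (log2 -1.06, interval -2.09 to -0.03), lower in 4 of 4 pairs. Most of that difference lay in wild-type 2, which had 226 Pygo1 counts while the other 7 libraries had 47 to 72. The list of 18 Wnt transcription machinery genes had 11 higher and 7 lower (median 0.05, camera adjusted p = 0.464), with Ssbp2 at 0.30 (SE 0.11) the member with the smallest p. Of 37 Wnt ligands and receptors 16 were higher and 21 lower (median -0.06, adjusted p = 0.542), among them Fzd9 at 0.75 (SE 0.34) and Rspo2 at -0.80 (SE 0.40). In both lists 0 genes passed when adjusted over the list alone.

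Of the 29 gene lists compared with all other genes, camera with its preset correlation called 12, 2 higher and 10 lower in mutants. With a correlation estimated per list 0 were called, and fry called 0. With the block 14 were called, 3 higher and 11 lower, and 0 with an estimated correlation or by fry. Of the members of these lists 0 passed over all genes, and 0 when adjusted over the list alone. The list calls below are made under the preset correlation, and with an estimated correlation 0 lists were called in any fit that left out 1 library.

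**Figure D2:**
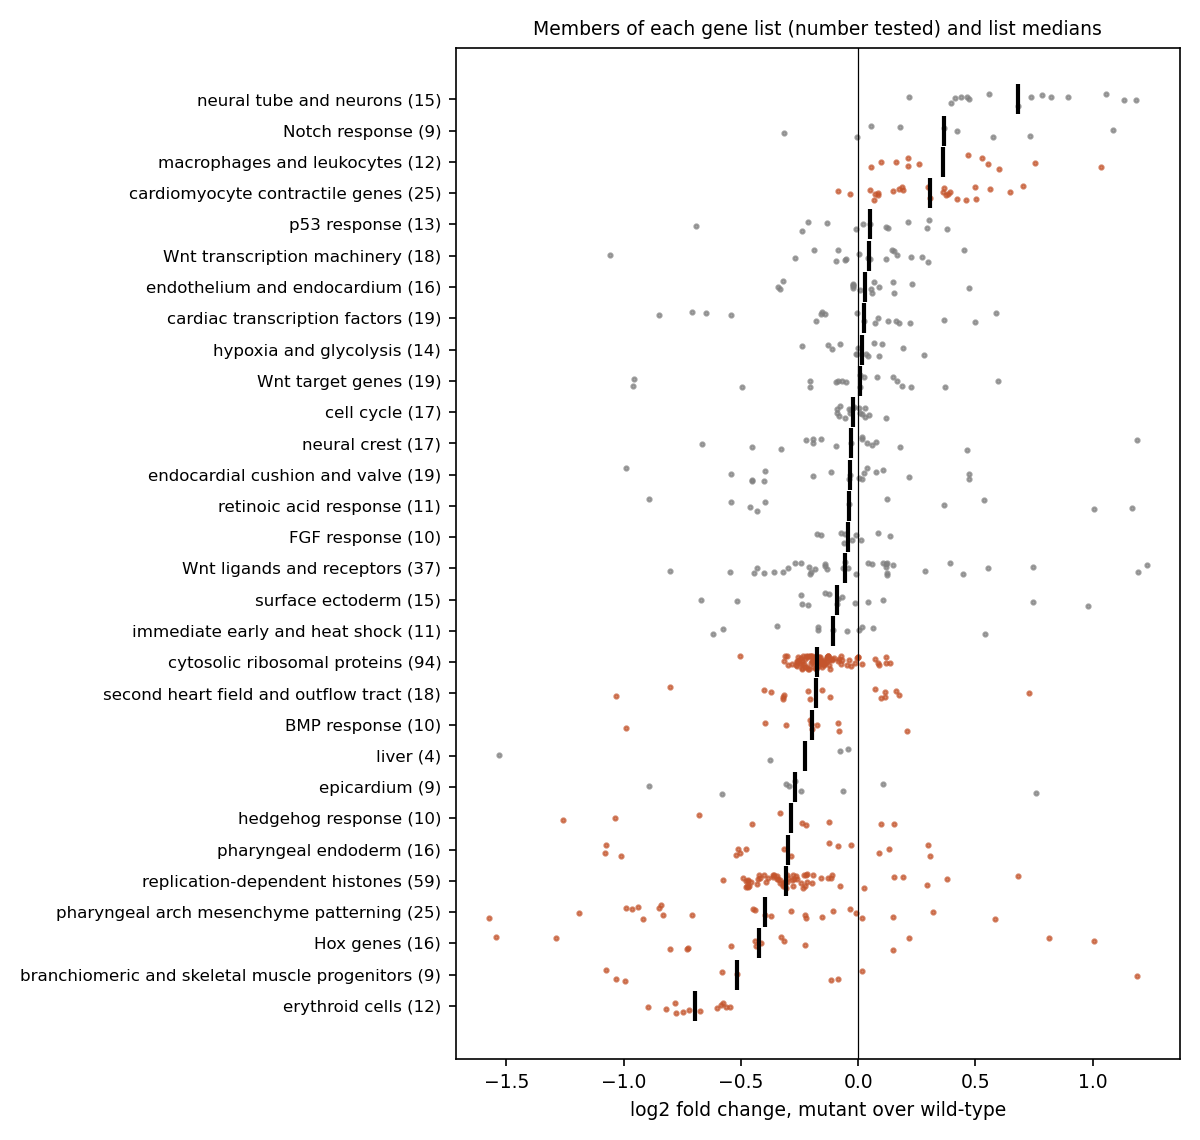
Log2 fold change (mutant over wild-type) of each tested member of 30 gene lists, with the number of tested members in parentheses and a black bar at the list median. Lists called by camera with its preset correlation are in orange; the medians run from -0.70 for erythroid genes to 0.68 for neural genes.

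Genes that pattern the arch mesenchyme fell as a list. Of 25 such genes 21 were lower in mutants, with a median log2 fold change of -0.40 (camera adjusted p = 1.64e-08; adjusted p = 0.286 with an estimated correlation). Msx1, a homeobox gene of the distal arches, was at 32.4 ± 12.2 CPM in wild-type and 16.3 ± 5.09 CPM in mutants (SD, n = 4 each; log2 -0.99, SE 0.31). Nkx3-2, a gene of the jaw joint, was at -0.92 (SE 0.30) and Hand2, a gene of the ventral arches and the heart, at -0.85 (SE 0.41), none of them passing alone. Adjusted over the list alone 0 members passed, and 5 did with the block. The mean log2 CPM of the list was 3.64 ± 0.402 in wild-type and 3.09 ± 0.159 in mutants (SD, n = 4 each), lower in 3 of 4 pairs, with an exact permutation p of 0.0857. The list median was -0.59 without wild-type 1 and -0.26 without wild-type 4.

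Related lists of the arches and their derivatives had the same sign. BMP response genes fell (9 of 10 lower, median -0.20, camera adjusted p = 0.00453; adjusted p = 0.286 with an estimated correlation), and 3 of these genes also sit in other lists, Msx1 among them. Id2, a direct BMP target, was at -0.31 (SE 0.17). The BMP call was lost without mutant 1 (adjusted p = 0.0608), and the median was -0.09 without wild-type 2 or mutant 4. Hedgehog response genes fell (8 of 10 lower, median -0.29, adjusted p = 0.00453; 0.328 with an estimated correlation), with Foxf1 at -1.26 (SE 0.53) and Gli1, a direct hedgehog target, at -0.33 (SE 0.19). That call was lost without wild-type 1 (adjusted p = 0.0572), wild-type 2 (0.0702) or mutant 3 (0.0928). Pharyngeal endoderm genes fell as a list (12 of 16 lower, median -0.30, adjusted p = 0.0135; 0.328 with an estimated correlation), although the keratin Krt8 was at 0.31 (SE 0.16) and Nkx2-3 at -1.01 (SE 0.53). Its call was lost without wild-type 1 (adjusted p = 0.113), wild-type 2 (0.0928) or mutant 1 (0.355, median -0.17).

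Progenitors of the head muscles and of the outflow tract were lower under the preset correlation. Branchiomeric and skeletal muscle progenitor genes fell (7 of 9 lower, median -0.52, camera adjusted p = 0.0227; adjusted p = 0.449 with an estimated correlation), with Myf5, a skeletal muscle determination gene, at -1.07 (SE 0.45). The call was lost without wild-type 1 (adjusted p = 0.0519), wild-type 2 (0.0802), wild-type 4 (0.252), mutant 3 (0.432) or mutant 4 (0.0762). Without wild-type 4 the median was 0.03, with 5 genes higher and 4 lower. Without mutant 3 it was -0.16, and without mutant 2 it was -0.86. Second heart field and outflow tract genes fell (11 of 18 lower, median -0.18, adjusted p = 0.0489; 0.449 with an estimated correlation), with Six2 at -0.80 (SE 0.36). Isl1, a marker of second heart field progenitors, was at 42.2 ± 7.5 CPM in wild-type and 47.6 ± 16.3 CPM in mutants (log2 0.17, interval -0.47 to 0.82), and Tbx1, a gene of the same field, at 0.12 (-0.43 to 0.66). That call was kept without wild-type 3 or mutant 2 and lost without any of the other 6 libraries, with adjusted p of 0.0572 and 0.317 without wild-type 1 and 2, 0.0888 without wild-type 4, and 0.126, 0.414 and 0.140 without mutant 1, 3 and 4. Its median ran from -0.16 to -0.07 over the 8 fits with a library left out. With the block, adjusted over the list alone, 3 second heart field genes and 1 muscle progenitor gene passed; without it 0 did.

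Genes of heart muscle contraction rose as a list while cardiac transcription factors did not move together. Of 25 contractile genes 23 were higher in mutants (median 0.31, camera adjusted p = 0.000763, or 0.690 with an estimated correlation). The list mean was 8.15 ± 0.523 log2 CPM in wild-type and 8.40 ± 0.632 in mutants (SD, n = 4 each). It was higher in 4 of 4 pairs, with an exact permutation p of 0.514. The mean of the Notch response list, which was not called, was also higher in 4 of 4 pairs. Ttn, the giant sarcomere protein titin, was at 5828 ± 2463 CPM in wild-type and 9123 ± 2955 CPM in mutants (SD, n = 4 each; log2 0.65, SE 0.33), and Myh7, a myosin heavy chain, was at 0.70 (SE 0.40). The contractile call was lost without wild-type 3 (adjusted p = 0.165), wild-type 4 (0.240), mutant 1 (0.862) or mutant 2 (0.115). Without mutant 1 the median was -0.03, with 11 genes higher and 14 lower, and without mutant 4 it was 0.52. Adjusted over the list alone 0 contractile genes passed, and 7 did with the block. Of 19 cardiac transcription factors 10 were higher and 9 lower (median 0.02, adjusted p = 0.369), while their mean log2 fold change, at -0.06, and the camera direction were lower. Nkx2-5, a core cardiac transcription factor, was at 13.8 ± 6.59 CPM in wild-type and 15.4 ± 9.71 CPM in mutants (log2 0.16, interval -1.01 to 1.33), and its sign differed in 5 of 22 other fits. Tbx3 was at -0.65 (SE 0.25) and Hand1 at -0.71 (SE 0.30). With the block 4 cardiac transcription factors passed when adjusted over the list alone, against 0 without. The median of the list was -0.26 without mutant 1 and 0.17 without wild-type 1. With the contractile list as a covariate its camera direction was lower. Under an estimated correlation it had the smallest camera p of the lists in that fit (unadjusted p = 0.0111, adjusted p = 0.276). The list was called lower without wild-type 3 (adjusted p = 0.0287; adjusted p = 0.531 with an estimated correlation) or mutant 2 (0.0343; 0.625 with an estimated correlation).

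Other tissues of the heart and arches did not differ as lists in the fit without the block. Endocardial cushion and valve genes had 9 higher and 10 lower (median -0.04, camera adjusted p = 0.209), among them Notch1 at 0.47 (SE 0.23) and Twist1 at -0.45 (SE 0.25), with 3 passing under the block when adjusted over the list alone. Endothelium and endocardium had 9 of 16 higher (median 0.03, adjusted p = 0.899), with Cldn5 at -0.33 (SE 0.18) and Nfatc1 at 0.47 (SE 0.40). Neural crest genes were split 8 to 9 (median -0.03, adjusted p = 0.452), with Pax7 at 1.19 (SE 0.87). Surface ectoderm had 11 of 15 lower (median -0.09, adjusted p = 0.0754; without wild-type 1 adjusted p = 0.00126, or 0.410 with an estimated correlation), with Tfap2c, an ectoderm and germline transcription factor, at -0.67 (SE 0.19) and Krt15 at 0.75 (SE 0.40). Epicardium had 7 of 9 lower (median -0.27, adjusted p = 0.0754), with Sema3d at -0.31 (SE 0.15) and Aldh1a2, an enzyme of retinoic acid synthesis, at -0.89 (SE 0.64). The epicardium list was called with the block (adjusted p = 0.0275; 0.637 with an estimated correlation), and also without wild-type 3 (0.000514), mutant 1 (0.0101) or mutant 2 (0.00156), where the adjusted p was 0.428, 0.583 and 0.458 with an estimated correlation. Its median was -0.59 without mutant 1, -0.07 without wild-type 2 and -0.02 without mutant 4, with 4 higher and 5 lower in that last fit.

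Markers of blood, macrophages and neural tissue varied between libraries. All 12 erythroid genes were lower in mutants and the list fell (median -0.70, camera adjusted p = 0.00219; adjusted p = 0.620 with an estimated correlation), with the embryonic globin Hbb-bh1 at -0.90 (SE 0.52). Wild-type 1 had the highest erythroid mean log2 CPM, 8.16, against 5.12 to 6.84 elsewhere, and without it the median was 0.19, with 9 of 12 genes higher (adjusted p = 0.957); the call was also lost without mutant 3 (0.0928) or mutant 4 (0.305). Macrophage and leukocyte genes rose (12 of 12 higher, median 0.36, camera adjusted p = 1.14e-06, or 0.328 with an estimated correlation). The mean of this list was higher in 4 of 4 pairs, with an exact permutation p of 0.0857. Mrc1 was at 0.75 (SE 0.28) and Aif1, with 0.263 and 0.546 CPM, at 1.03 (SE 0.40). The macrophage median was 0.23 without mutant 2. Of the neural tube and neuron genes 15 of 15 were higher (median 0.68) but the list was not called (camera adjusted p = 0.243). Its mean log2 CPM ranged from -0.23 to 4.47 over libraries. Neurod1 was at 0.89 (SE 0.83) and Elavl4 at 0.82 (SE 0.85). The neural list was called higher with the block (adjusted p = 0.0231; 0.684 with an estimated correlation), without wild-type 3 (0.000846; 0.507 with an estimated correlation) and without mutant 1 (1.76e-07; 0.583 with an estimated correlation). Its median was 1.72 without wild-type 3, 0.23 without mutant 3 and 0.26 without mutant 4. The 4 liver genes measured were all lower and not tested as a list, with Apob at -0.38 (SE 0.18) and Afp at -1.53 (SE 1.04).

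Hox genes, which mark the position of a segment along the body, fell as a list (12 of 16 lower, median -0.42, camera adjusted p = 0.000309; adjusted p = 0.449 with an estimated correlation). Hoxb6, at 0.640 ± 0.397 and 0.213 ± 0.331 CPM (SD, n = 4 each), was at -1.54 (SE 0.96). Without mutant 1, which had a Hox mean log2 CPM of -0.90 against 0.60 to 2.25 in the other 7 libraries, the list was not called (adjusted p = 0.363) and its median was -0.03, with 7 higher and 9 lower. The Hox median was -0.88 with the block and -1.26 with limma-voom. Retinoic acid response genes had 5 higher and 6 lower (median -0.04, mean 0.04, adjusted p = 0.452), with Cyp26b1, which degrades retinoic acid, at 1.17 (SE 0.44) and Rdh10, an enzyme of its synthesis, at -0.40 (SE 0.21).

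Replication-dependent histone genes, whose mRNA is made in S phase and lacks a poly(A) tail, fell as a list with the smallest p of the lists tested. Of 59 measured 53 were lower in mutants, with a median log2 fold change of -0.31 (camera adjusted p = 2.61e-20; adjusted p = 0.328 with an estimated correlation). Hist2h4 was at 154 ± 17.3 CPM in wild-type and 110 ± 14.2 CPM in mutants (SD, n = 4 each; log2 -0.49, SE 0.12), without overlap. Hist1h4f was at -0.57 (SE 0.17), Hist1h2bh at -0.39 (SE 0.11) and Hist1h1d, a linker histone, at -0.48 (SE 0.14). Adjusted over the list alone 0 histone genes passed, and 34 did with the block. The list mean was lower in 4 of 4 pairs, at 6.92 ± 0.211 and 6.64 ± 0.261 log2 CPM (SD, n = 4 each), with an exact permutation p of 0.171. The list median was -0.18 without wild-type 3 and -0.46 without mutant 3. Histone genes are near-identical copies, so reads can be shared between members. Cytosolic ribosomal protein genes also fell (87 of 94 lower, median -0.17, adjusted p = 1.54e-15; 0.449 with an estimated correlation), with Rpl14 at -0.30 (SE 0.12); the median was -0.11 without wild-type 3, -0.07 without mutant 1 and -0.26 without mutant 3.

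**Figure D3:**
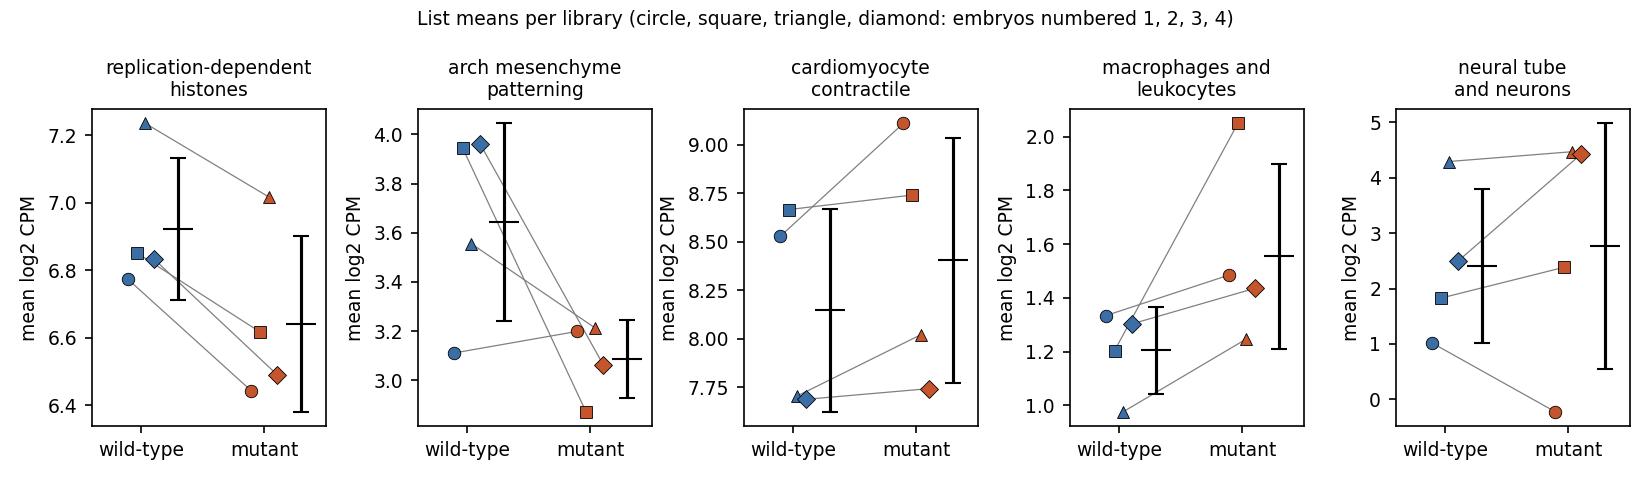
Mean log2 CPM of 5 gene lists in each library, with lines joining libraries of the same number and bars showing the mean ± SD of 4 libraries per group. The histone mean was lower and the contractile and macrophage means higher in the mutant of 4 of 4 pairs, the arch patterning mean was lower in 3 of 4, and the neural mean ran from -0.23 to 4.47.

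Cell cycle and stress genes gave no call. Cell cycle genes had 7 higher and 10 lower (median -0.02, camera adjusted p = 0.759), with Plk1 at 0.12 (SE 0.12) and Birc5 at -0.09 (SE 0.14). The p53 response had 8 of 13 higher (median 0.05, adjusted p = 0.542), with Cdkn1a at 0.30 (SE 0.16) and Pmaip1, which promotes cell death, at -0.69 (SE 0.23). Immediate early and heat shock genes had 7 of 11 lower (median -0.11, adjusted p = 0.147), with Hspa1b at -0.58 (SE 0.35) and Hspa1a at -0.62 (SE 0.40); they were called lower without wild-type 3 (0.00805) or mutant 1 (0.0485), where the adjusted p was 0.333 and 0.583 with an estimated correlation. Hypoxia and glycolysis genes were split 7 to 7 (median 0.01, adjusted p = 0.701), with Egln3 at -0.24 (SE 0.22) and Slc2a1 at 0.28 (SE 0.26). FGF response genes had 7 of 10 lower (median -0.04, adjusted p = 0.542), with Dusp6 at -0.16 (SE 0.18) and Etv4 at -0.17 (SE 0.22). Notch response genes had 7 of 9 higher (median 0.37, adjusted p = 0.136), with Heyl at 0.42 (SE 0.28) and Hes1 at -0.32 (SE 0.15), and were called higher without wild-type 3 (0.0469; adjusted p = 0.428 with an estimated correlation). The Notch median was 0.17, 0.20 and 0.19 without mutant 1, 3 and 4. Of these 6 lists 0 members passed, over all genes or adjusted over the list alone.

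The genes with the smallest p after Pygo2 did not pass and are given as values. Among those lower in mutants, Gdf6, a BMP family growth factor, was at 9.87 ± 4.46 CPM in wild-type and 4.70 ± 0.872 CPM in mutants (SD, n = 4 each; log2 -1.07, SE 0.30), and Nr5a2, a nuclear receptor, was at -1.33 (SE 0.38). Pla2g4a, a phospholipase, was at -0.52 (SE 0.13), the netrin receptor Unc5c at -0.51 (SE 0.15) and the chromatin protein Hmga2 at -0.36 (SE 0.11). Among those higher, Map1a, a microtubule protein of neurons, was at 24.0 ± 5.96 CPM in wild-type and 37.6 ± 4.78 CPM in mutants (log2 0.65, SE 0.19). Adamtsl2 was at 0.75 (SE 0.22) and Myo16 at 1.05 (SE 0.36). Cytl1 was at 1.59 (SE 0.52), with 0.525 and 1.58 CPM. The values of Atp6v0e2, Fam212b, Aldh1l2, 3632451O06Rik and 1700019G17Rik lay between 0.45 and 0.64.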

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

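The counts of genes called in other splits of the 8 samples, and the comparison with 0 of the arch median under the contractile covariate, were tests chosen only after the result was seen; the other tests in this part were not.

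Of 226 groups of 4 libraries, 1 library lay far from the other 3 in 21, where chance alone gives 11.3, or 1 in 20. Mutant 1 was apart in 8 of these 21 values. In mutant 1, Lef1 was at 31.8 CPM (18.5 to 20.7 in the other mutants), Twist1 at 49.7 CPM (25.5 to 28.1), Nr5a2 at 4.39 CPM (1.55 to 1.73), Myf5 at 3.26 CPM (1.21 to 1.44) and Slc2a1 at 395 CPM (182 to 218), and the retinoic acid list had a mean log2 CPM of 2.88 (3.69 to 3.85). In wild-type 2, Pygo1 was at 9.57 CPM (2.59 to 3.52 in the other wild-type libraries) and Gdf6 at 16.5 CPM (6.99 to 8.26). In wild-type 1, Bcl9l was at 20.4 CPM (15.8 to 16.4). In wild-type 3, Lef1 was at 18.7 CPM (25.2 to 26.5) and Gli1 at 22.01 CPM (33.6 to 35.9), and the histone list had a mean log2 CPM of 7.24 (6.77 to 6.85). In mutant 3, Hist2h4 was at 131 CPM (102 to 104 in the other mutants) and Adamtsl2 at 4.71 CPM (6.79 to 7.14). In mutant 2, Foxf1 was at 24.2 CPM (7.10 to 8.88) and Hoxb6 at 0.704 CPM (0 to 0.108), and in mutant 4 the liver list had a mean log2 CPM of 0.0497 (1.80 to 1.94). The ribosomal RNA precursor Rn45s took 4.83% of the counts in wild-type 4 (0.523% to 0.643% in the other wild-type libraries) and 1.29% in mutant 1 (0.491% to 0.597%). Lars2 took 0.521% in wild-type 4 (0.00301% to 0.00402%) and 0.0330% in mutant 1 (0.00327% to 0.00386%).

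The drop of Pygo2 rests on the size of its fold change and its edgeR quasi-likelihood test. The counts of genes and lists can be set beside other splits of the same samples. Of the 35 splits into 4 and 4, 3 called as many genes as the real split, which called 1, and the highest other called 4102. For genes lower in mutants 3 splits gave as many as the real 1, with 2183 the highest other. For lists called, 11 of 35 splits gave as many as the real 12, with 19 the highest other, so chance is not excluded for these counts. For genes higher the real count is 0, which all 35 splits must reach, so the splits test nothing there (2183 the highest other). The split with 4102 genes sets the libraries numbered 1 and 2 against those numbered 3 and 4 and points to a structure of the samples; with the number as a block, Pygo2 remained the only gene called (adjusted p = 0.00241). With the numbers taken as pairs, as inferred from the data, the 7 other splits that part all pairs called 0 genes and 2 to 10 lists. The 27 remaining splits called 0 to 4102 genes and 2 to 19 lists.

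Replication-dependent histone genes were lower in mutants, with a median log2 fold change of -0.31. A length under 1973 bases as the whole cause is argued against by 1466 other genes up to that limit. Their median was -0.0658 (SE 0.0047). Ribosomal protein genes (median -0.17) and short RNAs without a poly(A) tail, both lower, were left out of them. The limit was taken from the annotated exon lengths of the histone genes, which differ widely (391 bases for Hist1h4f, 7425 for Hist1h1d). Shorter lengths were not tested apart, so an effect of very short length stays open. Against fewer cells in S phase as the whole cause stand 26 S phase genes, whose median was -0.0506 (SE 0.017, 19 lower). That is closer to 0 than the bound of -0.15 set beforehand by more than 2 standard errors. The point needs these genes to follow the number of S phase cells about as closely as histone mRNA does. That was not tested, so fewer S phase cells stay open. These standard errors come from resampling genes and leave out variation between embryos. Both points thus hold for these 8 libraries only. Recovery of RNA without a poly(A) tail stays open. A set of 102 other short RNAs of that kind, such as small nucleolar RNAs, had a median of -0.16 (SE 0.019, 80 lower). That is past the bound of -0.15 set beforehand by less than its standard error. Many of these RNAs were measured at a few CPM or less. The most abundant, named after their values were seen, were Rmrp at -0.29, Rpph1 at -0.51, Snord17 at -0.48 and Rprl3 at -0.43. The next were Snord15b at -0.23, Snora74a at -0.43, Scarna10 at -0.51 and Snord22 at -0.19. In 6 of 35 splits the histone median was as far from 0, with 0.43 the highest other, so chance is not excluded; among the 7 other splits that part all pairs it was 0.02 to 0.17 from 0. An effect of the Pygo2 mutation is also open.

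Arch patterning genes were lower in mutants, with a median log2 fold change of -0.40. Less mesenchyme in the dissection as the whole cause is argued against by 16 genes of arch and body mesenchyme. Their median was 0.00514 (SE 0.051, 8 lower). These genes are not confined to the arches, so less arch mesenchyme offset by other mesenchyme stays open. The standard errors of medians here come from resampling genes and leave out variation between embryos. More heart tissue in the mutant libraries, as the whole cause, is argued against: with the contractile list as a covariate, which moved the contractile median from 0.31 to -0.03, the arch median was -0.42 (SE 0.15, 22 of 25 lower; camera adjusted p = 9.85e-06, or adjusted p = 0.312 with an estimated correlation). A part in it stays open, since the bound of -0.20 set beforehand lies within 2 standard errors, and so does a smaller share of distal arch tissue: 17 distal and midline genes, which overlap with the list itself, had a median of -0.71 (14 lower). In 5 of 35 splits the median was as far from 0, with 0.69 the highest other, so chance is not excluded; among the 7 other splits that part all pairs it was 0.01 to 0.69 from 0, and genotype stays open too.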

How the results depend on the processing

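Removal of structural RNAs, the neural covariate, the exact test of edgeR, the omission of pair 4 and the estimated correlation with a library left out or with a covariate were tests chosen only after the result was seen.

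Pygo2 fell in every fit. Its log2 fold change was -1.46 to -1.35 with each library left out, when 0 to 1 genes changed and 0 to 1 were lower, and the call was lost in 5 of these 8 fits, which have fewer samples. Without pair 4 it was -1.40 (adjusted p = 0.140), with 0 genes changed and 0 lower. In the other alternatives the fold was -1.46 to -1.38 and Pygo2 the only call. With the number as a block it was -1.40, with 1 gene called and 14 lists; of single lists the block changed the calls of the neural and epicardium lists, and besides the counts adjusted over a list alone it changed no other call. Camera with an estimated correlation called 0 lists and fry 0; under the preset correlation the alternatives called 9 to 18 lists, and 8 to 17 with a library left out. The arch patterning, macrophage, histone and ribosomal protein lists were called in all 8 such fits, the other 8 called lists not. With the contractile list as covariate the direction of that list was lower (adjusted p = 0.813), by the covariate's construction. That fit called 18 lists under the preset correlation, against 12 in the main fit. It had 1037 genes at an unadjusted p under 0.05, against 193. With an estimated correlation it called 0 lists. Among the lists it gained, endothelium was called lower (camera adjusted p = 0.0247, or 0.433 with an estimated correlation). The cause was not tested. Over lists and alternatives 546 values kept direction and call, 27 gained a call, 62 lost it and 2 reversed. Of 79 named genes that did not pass, 70 kept their sign throughout. At this depth and spread, most 1.5-fold changes would be missed: simulated ones were recovered in 12% of genes.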

Other observations

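The gene counts over splits of the samples were tests chosen only after the result was seen, as were the comparison of the libraries numbered 3 and 4 with those numbered 1 and 2 and the count near Pygo2 without certain RNA classes.

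Marker genes of several tissues differed between the embryos numbered 3 and 4 and those numbered 1 and 2. With genotype as a term, 3804 genes differed at an adjusted p under 0.05 (edgeR quasi-likelihood), 1757 higher and 2047 lower in 3 and 4. This fit takes the 8 libraries as independent although same-numbered ones vary together, so its p-values can be too small. The grouping is that of the split with 4102 called genes, so the counts describe that split and do not test it anew. Contractile genes were lower (25 of 25, 24 of them called, median log2 fold change -0.95), as were cardiac transcription factors (16 of 19, 13 called, median -0.89), epicardium (9 of 9, 8 called, median -1.27), endothelium and endocardium (16 of 16, 10 called, median -0.60) and erythroid genes (12 of 12, 8 called, median -1.38). Hypoxia and glycolysis genes were lower too (13 of 14, 9 called, median -0.51). Neural genes were higher (15 of 15, 10 called, median 2.23), and so were cell cycle genes (16 of 17, 10 called, median 0.35) and ribosomal protein genes (82 of 94, 35 called, median 0.31). Camera with its preset correlation called 12 lists, these 9 and 3 more: histone genes (53 of 59 higher, 2 called, median 0.21, adjusted p = 0.00203), the Wnt transcription machinery (15 of 18 lower, median -0.32, adjusted p = 0.0455) and Wnt ligands and receptors (25 of 37 lower, median -0.30, adjusted p = 0.0455). With an estimated correlation the adjusted p-values were 0.323 for contractile genes, 0.122 for cardiac transcription factors, 0.326 for epicardium, 0.148 for endothelium, 0.555 for erythroid genes, 0.148 for hypoxia, 0.445 for neural genes, 0.299 for the cell cycle and 0.445 for ribosomal proteins, 0.697 for histones, 0.505 for the Wnt machinery and 0.326 for Wnt ligands and receptors, so 0 were called. Arch patterning genes were at 0.05, and Pygo2 was at -0.23 (adjusted p = 0.0675). The first principal component held 53.3% of the variance. The labels do not say what the numbers stand for.

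Both sexes were present in both groups. Xist had 27265 to 33741 counts in wild-type 2, wild-type 3 and mutant 4, where 4 Y-linked genes summed to 19 to 24 counts. In the other 5 libraries Xist had 46 to 121 counts and the Y-linked genes 7505 to 10844.

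The authors' deposited list of 165 gene ontology terms counts their first 500 genes; the 5 terms given here were chosen after their values were seen. It gives heart development 34 genes against 11.1 expected, embryonic morphogenesis 49 against 12.7, embryonic limb morphogenesis 22 against 3.03 and nucleosome assembly 13 against 1.64. Sensory perception of smell had 3 genes against 23.6 expected. That expected number points to a reference set wider than the genes expressed in this tissue. Many sets of genes expressed here could then show such contrasts, so they are not shown to come from the ranking. Of these 500 genes only Pygo2 passed the threshold in the authors' deposited table.

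A related count was made in the fit of the raw counts, with 18 developmental lists chosen from the fixed ones after their results had been seen. Of their 249 tested genes 30 were among the 500 genes with the smallest p, where 8.38 are expected at random. Variation between embryos or dissections unrelated to genotype could give as many: in 7 of the 35 splits of the samples as many were found, with 50 the highest other, so chance is not excluded. The median of the other splits was 16.5 genes, and among the 7 other splits that part all pairs it was 12 to 40.

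A hypothesis was that an altered genome around the targeted gene moves its neighbours. Of 236 genes within 10 Mb of Pygo2, leaving out Pygo2, Tmod4 and Hist2h4, 6 had an unadjusted p under 0.05 (2.54%), a larger share than in 87.6% of 13697 windows elsewhere, whose median was 1.09%. The bounds set beforehand were the median and 95% of the windows, and the share lies between them, so the hypothesis stays open. Tmod4, named above from the authors' deposited table, lies 5.69 Mb from Pygo2 and had a log2 fold change of -1.97. Hist2h4 lies 6.83 Mb away and was at -0.49. Both ranked ahead of the 6 counted genes by unadjusted p, so leaving them out lowers the share. The share with Tmod4 and Hist2h4 kept was not set against the windows. Of the 6 genes, named here after their values were seen, Hist2h2ac is a replication-dependent histone gene and Terc an RNA of the short non-polyadenylated list, classes with lower medians in mutants. With both classes left out everywhere, 4 of 227 genes remained (1.76%), a larger share than in 77.2% of 13536 windows.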
